A study of Homo sapiens with 6 samples.

How the data were processed

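Monocytes had been isolated with magnetic beads from the blood of 3 healthy donors before and after a dietary oxalate load, and total RNA was sequenced, per the labels' protocols. The deposited table held whole-number counts of reads per gene for 6 libraries, 1 pre-load and 1 post-load library for each of the 3 donors. Base calling with bcl2fastq 2.18.0.12, alignment with STAR 2.6.1b to GRCh38 and counting with HTSeq 0.11.0 were listed per the submitters' processing notes, which also named DESeq2 1.20.0. The annotation release and the strandedness of the counting are not given in the sources used here, nor are the dose, the interval between the samples and the time of day.

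The deposited counts covered 58096 lines that named a gene. Of these, 45 repeated a gene identifier, with at most 1 count summed over the libraries, and were added together, which left 58051 identifiers. Symbols were matched for 57447 of them from GENCODE release 29 and current symbol tables, and gene positions are those of GENCODE release 29 on GRCh38. In all, 517 genes (Y chromosome, XIST and TSIX) were left out because the donors are human. The 5 summary lines that name no gene stayed out of library sizes and tests. Reads in no annotated feature made up 10.1% to 21.4% of a library's total, and reads without a unique alignment 14.2% to 24.7%. Reads that overlapped more than 1 gene, and were counted for none, made up 5.46% to 6.35%. Counts in genes ranged from 23621901 to 30621063 per library. Counting of this kind drops or splits reads shared between near-identical or overlapping genes, so HSPA1A, RPS10, NDUFV2, THBS1-IT1, RN7SKP296 and pseudogenes carry uncertain values. Without a stated strand setting the same holds for NDUFS7, XAF1, SQSTM1, DUSP6, DDIT4, RPL30, IL6, NDUFB3, MMP9, HVCN1 and PER3, which share 16.7% to 49.1% of their exon bases with genes on the opposite strand.

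Genes were kept with edgeR's filterByExpr by time point (minimum count 10, minimum total 15), which left 17260, and libraries were scaled with TMM. The test was edgeR's quasi-likelihood test with robust shrinkage, two-sided, with donor as a block and time point as the tested term, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic, and n is 3 donors. The SE of a list's median within a donor, or of a difference of such medians, comes from the spread over the genes, taken as independent. It does not measure error between donors or libraries, and is too small where the genes of a list move together. Levels are CPM, counts scaled to the library's normalised total, as mean and SD over 3 libraries, and changes within a donor are differences of log2 CPM with a prior count of 2. The tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and Python 3.11.15. An exact permutation of 6 libraries gives 10 splits, so no share under 0.1 can arise, and only 4 of the 10 part all 3 pairs.

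The block follows from the series title and design, which describe the same subjects before and after the load, and from donor numbers shared by a pre-load and a post-load library. The pairing was checked by correlating each library's deviations from its time point's mean. These correlations were 0.306, 0.696 and 0.606 within donors 1, 2 and 3, and between -0.567 and 0.096 across donors.

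The tests, their alternatives, 23 functional lists, 10 cell type lists and the rule for named genes were chosen before the data were examined. Of 820 list memberships, 818 matched a gene identifier. Each list with at least 5 tested genes was tested with camera (preset correlation 0.01, Benjamini-Hochberg over 33 lists), with camera and an estimated correlation, and with fry. The named genes were, first, the 10 largest log2 changes in each direction among genes past the threshold that moved the same way in 3 donors. The rule added the 3 members of each list with the smallest p, and IL1B, TNF, IL6, CXCL8, IL10, NLRP3, SOD2, HMOX1, CD14, FCGR3A, MT-ND1, MT-CO1 and SLC26A6. Some genes that the rule names are not reported here. Genes without a symbol were not named, and immunoglobulin, T cell receptor and HLA genes were named only as list members. Other list members and gene families in the text were picked after their values were seen, and are said to have been.

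The alternatives were a fit without the donor block, DESeq2 size factors, total counts alone, no filter, at least 50 counts in 3 libraries, the DESeq2 Wald test, limma-voom, edgeR's likelihood ratio test, no robust shrinkage, removal of mitochondrial, globin and receptor genes, a threshold of 0.10, and each donor left out. With a donor left out the fit has fewer residual degrees of freedom, and its p-values measure the spread between donors poorly. The smallest edgeR adjusted p was 0.000301 without donor 1, 1.14e-30 without donor 2 and 2.61e-26 without donor 3, against 3.68e-05 with all donors. Calls kept or gained in such fits are therefore weak evidence. GC content and length offsets (splines with 5 degrees of freedom) and a T cell marker score were added after the data were seen. Each entered beside the donor block, the score as a covariate. The score takes up a residual degree of freedom, so calls kept or gained with it are weak evidence as well. The pipeline was tested on simulated data for the post-load against pre-load comparison, with 200 of 16715 genes changed. It recovered 59% of genes changed by a factor of 2 and 97% of those changed by a factor of 4, and called 15 unchanged genes. The changed genes were drawn above a minimum mean count, so the recovery does not cover genes with few reads. With no change simulated it called 5 genes and 0 lists. Genes were simulated independently of each other, so the 0 cannot show how often lists of genes that move together are called falsely. In the real data the estimated correlation was 0.966 for the mitochondrial genome list and 0.871 for T cell markers.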

Results

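RNA from blood monocytes of 3 healthy donors was sequenced before and after a dietary oxalate load. Oxalate is a plant-derived acid that forms calcium oxalate crystals in urine. The series compares the monocyte transcriptome of the same subjects at the 2 time points, with 3 libraries at each. Counts in genes were 25771957 before and 26716445 after the load in donor 1, 23621901 and 30621063 in donor 2, and 25343523 and 25561171 in donor 3. The libraries grouped first by donor, on a component holding 41.2% of the variance of log2 CPM, and then by time point, on a component holding 29.6%.

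**Figure D1:**
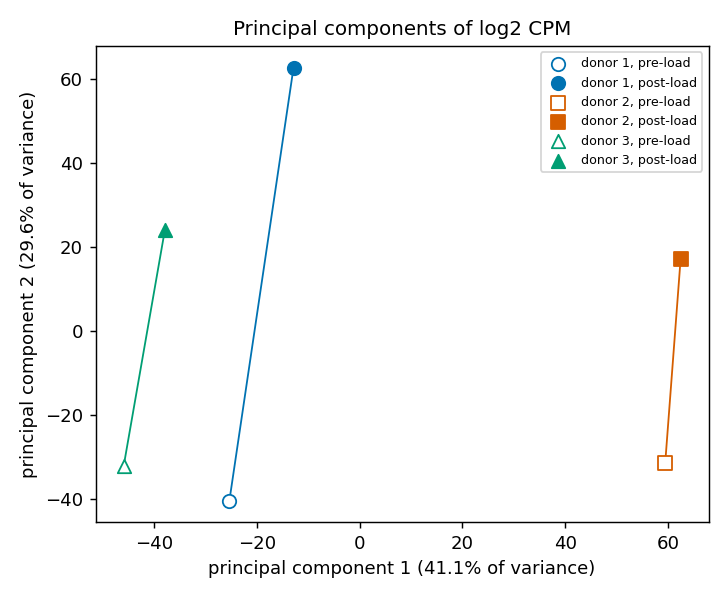
Principal components 1 (x axis, 41.2% of variance) and 2 (y axis, 29.6% of variance) of log2 CPM in 6 libraries, with open symbols before and filled symbols after the load and a line joining each donor's pair. Component 2 runs from -40.4, -31.4 and -32.3 before the load to 62.8, 17.3 and 24.0 after it in donors 1, 2 and 3.

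GIMAP7, CX3CR1 and CCR2 rose after the load, while THBS1, CH25H and AREG fell. GIMAP7, a GTPase of the immunity-associated family, rose 10.7-fold, from 5.82 ± 2.04 to 66.3 ± 38.8 CPM (SD, n = 3 donors). CX3CR1, the fractalkine receptor that marks patrolling monocytes, rose 6.42-fold (log2 2.68, SE 0.14), and CCR2, the CCL2 receptor that draws monocytes out of the marrow, rose 6.60-fold (log2 2.72, SE 0.26). CH25H, which makes an oxysterol from cholesterol, fell by 4.13 on the log2 scale (SE 0.33), from 8.12 ± 4.30 to 0.502 ± 0.444 CPM. THBS1, which encodes the matrix glycoprotein thrombospondin, fell by 3.15 (SE 0.22), from 759 ± 565 to 91.9 ± 79.7 CPM.

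By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1686 of 17260 genes changed, 782 higher and 904 lower after the load. All 1686 moved the same way in the 3 donors. Passing a paired test largely requires this, so it is not separate evidence. A change of at least 2-fold was reached by 285 of the higher and 442 of the lower genes. The edgeR adjusted p was 3.68e-05 for GIMAP7 and CX3CR1, 0.000902 for CCR2, 0.000382 for CH25H and 0.000213 for THBS1. On GRCh38 (GENCODE release 29) GIMAP7 (ENSG00000179144) lies on chromosome 7 at 150514830 to 150521073, CX3CR1 (ENSG00000168329) on chromosome 3 at 39263494 to 39281735 and CCR2 (ENSG00000121807) on chromosome 3 at 46353734 to 46360928. CH25H (ENSG00000138135) lies on chromosome 10 at 89205629 to 89207314 and THBS1 (ENSG00000137801) on chromosome 15 at 39581079 to 39599466. The counts are per gene over its annotated exons.

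The other genes with the largest rises were HSPA1A (log2 2.51, SE 0.24), an inducible heat shock chaperone with a near-identical neighbouring copy, CD180 (2.46, SE 0.17), a homologue of toll-like receptors, and the zinc finger gene ZNF2 (2.28, SE 0.35). TEDC2-AS1 (2.61), the Wnt ligand WNT6 (2.30), the peroxisomal membrane gene PEX11A (2.29) and KL (2.24), which encodes klotho, rose from levels between 0.132 and 0.171 CPM. ZBTB16, a zinc finger transcription factor, fell by 3.09 (SE 0.35), and AREG, a ligand of the epidermal growth factor receptor, fell by 2.68 (SE 0.24). The intronic transcript THBS1-IT1 fell by 3.73, and lies inside the THBS1 gene. HOXA5 (fell by 2.89), LINC00484 (fell by 2.88), RN7SKP296 (fell by 3.34), DUTP2 (fell by 2.79) and BNIP3P25 (fell by 2.72) had at most 1.38 CPM before the load. The last 3 are annotated copies or pseudogenes whose reads cannot be assigned with certainty. RN7SKP296 also lies inside the IL1RAP gene, on the same strand. IL1RAP fell as well, so the fall of RN7SKP296 may not be separate. With 1 donor left out, edgeR calls were lost for KL and TEDC2-AS1 (without donor 1 or 3, adjusted p up to 0.135 and 0.133), WNT6, ZBTB16 and DUTP2 (without donor 1, 0.0623 or more) and PEX11A (without donor 2, 0.0580). Immunoglobulin, T cell receptor and HLA genes accounted for 2 of the calls. Without the donor block edgeR called 0 genes, with 2523 at an unadjusted p under 0.05, and without donor 1 it called 939. With total counts alone in place of TMM the edgeR calls of 34 named genes were lost, with adjusted p from 0.0504 (ULK1) to 0.0885 (CLEC10A). Of these HOXA5 (0.0531), FUNDC1 (0.0513), IL1RAP (0.0560), MAP3K8 (0.0523), XAF1 (0.0664) and ACSL1 (0.0631) kept their calls with each donor left out.

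**Figure D2:**
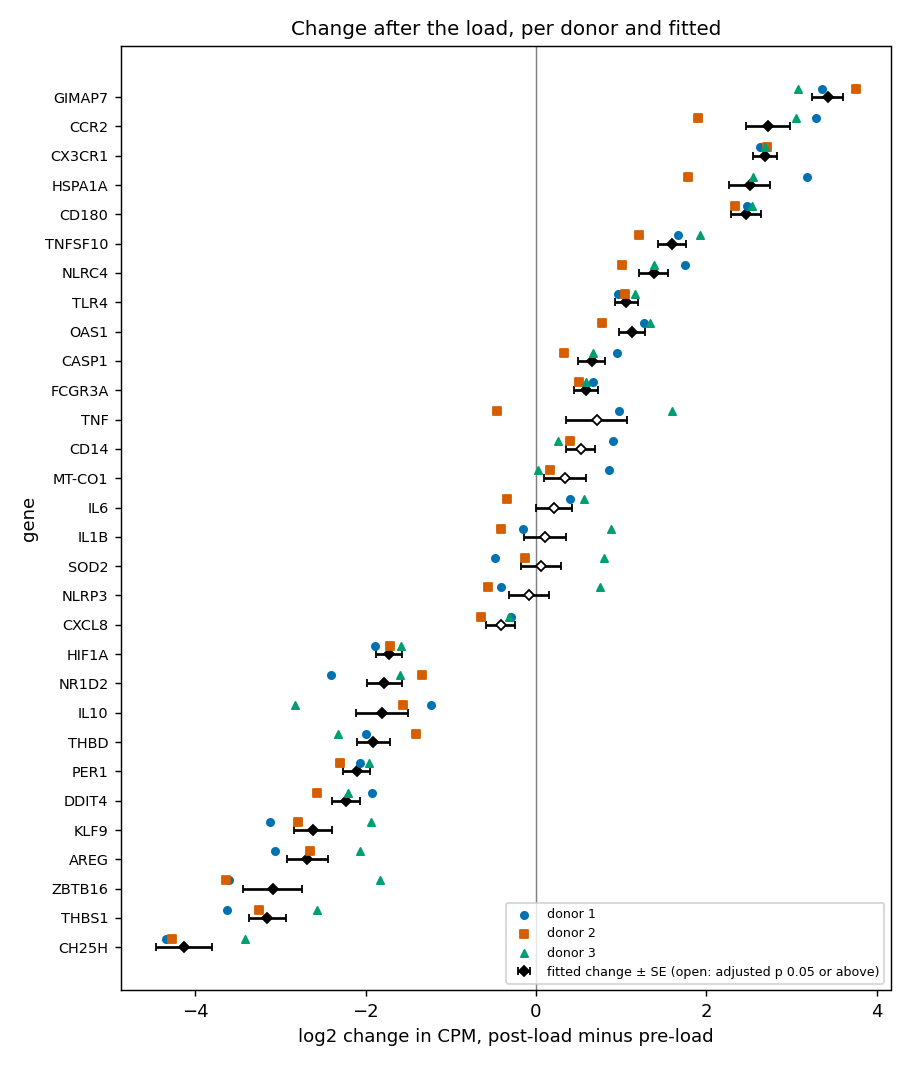
Log2 change in CPM (x axis, post-load minus pre-load) of 30 named genes (y axis), with diamonds for the fitted change ± SE, coloured symbols for the 3 donors and open diamonds where the edgeR adjusted p was 0.05 or above. GIMAP7 (3.42) and CH25H (-4.13) mark the ends, and IL1B (0.10) and NLRP3 (-0.08) lie near 0.

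Of 18 tested circadian clock genes 10 fell, 0 rose and 8 did not pass, and 11 fell when adjusted over the list alone. The repressor PER1 dropped by 2.11 on the log2 scale (SE 0.16), from 1462 ± 188 to 344 ± 78.4 CPM, and the nuclear receptor gene NR1D2, which represses BMAL1, dropped by 1.78 (SE 0.20). PER3, a further period gene, dropped by 1.34 (SE 0.21). The genes BMAL1 (log2 -0.09, SE 0.14) and CLOCK (-0.10, SE 0.16), picked after their values were seen, did not pass, while NFIL3, a repressor picked in the same way, fell by 0.72 (SE 0.17, edgeR adjusted p 0.0302). Among the 10 called genes, calls were lost for CSNK1D without each of the 3 donors (adjusted p up to 0.134), NR1D1 and PER2 without donor 1 (0.0503 and 0.0874), NFIL3 without donor 2 (0.165) and DBP without donor 3 (0.134). The edgeR adjusted p was 0.000367 for PER1, 0.00292 for NR1D2 and 0.00885 for PER3, and PER1 (ENSG00000179094) lies on chromosome 17 at 8140472 to 8156506. The list median was -0.68 (-0.78, -0.68 and -0.73 in donors 1, 2 and 3), with a camera adjusted p of 2.87e-11 at the preset correlation. Its adjusted p = 0.398 with an estimated correlation.

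Of 17 tested glucocorticoid-induced genes 7 fell and 0 rose, and 10 fell when adjusted over the list alone. KLF9, a steroid-inducible transcription factor, dropped by 2.62 (SE 0.22), from 100.2 ± 11.6 to 17.5 ± 8.19 CPM, and THBD, the thrombin receptor thrombomodulin, dropped by 1.91 (SE 0.19). ZBTB16 and PER1, named above, are members as well. Among members picked after their values were seen, FKBP5, a co-chaperone of the steroid receptor, dropped by 1.61 (SE 0.28) and the chemokine receptor CXCR4 by 1.41 (SE 0.19). By edgeR the adjusted p was 0.000565 for KLF9, 0.00133 for THBD and 0.00341 for ZBTB16. The list median was -0.69 (-0.56, -0.79 and -0.66 by donor), the camera adjusted p was 5.36e-12, and the adjusted p = 0.398 with an estimated correlation. Without donor 1 the calls of ZBTB16 and SAP30 were lost, with edgeR adjusted p of 0.0739 and 0.0514.

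The cytokine genes IL1B, IL6, CXCL8 and TNF did not pass. IL1B differed by 0.10 on the log2 scale (SE 0.25), IL6 by 0.21 (SE 0.21), CXCL8 by -0.41 (SE 0.17), and TNF by 0.72 (SE 0.36), with -0.45 in donor 2 against 0.97 and 1.59 in donors 1 and 3. Without donor 2, TNF passed at 1.29, with an edgeR adjusted p of 0.000544. NLRP3, the sensor of the crystal-activated inflammasome, differed by -0.08 (SE 0.23). Of 22 inflammasome and IL-1 family genes 4 rose and 1 fell, and 7 rose and 3 fell when adjusted over the list alone. NLRC4, a sensor of bacterial proteins, rose by 1.38 (SE 0.17), CASP1, the protease that processes IL1B, rose by 0.65 (SE 0.16), and IL1RAP, a receptor subunit, fell by 1.43 (SE 0.29). AIM2 (0.87) and CASP4 (0.55), picked after their values were seen, were the other members that rose. The edgeR adjusted p was 0.00367 for NLRC4, 0.0332 for CASP1, 0.0230 for IL1RAP, 0.823 for IL1B, 0.243 for TNF, 0.550 for IL6, 0.149 for CXCL8 and 0.856 for NLRP3. The list passed camera with an adjusted p of 0.0477, median 0.23, and its adjusted p = 0.986 with an estimated correlation. It lost its call without donor 1 and without donor 3, with camera adjusted p of 0.0542 and 0.680. Calls were lost for AIM2 without each of the 3 donors (edgeR adjusted p up to 0.0725), for CASP1 without donor 1 or 3 (0.0643) and for CASP4 without donor 3 (0.209).

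Of 25 cytokine and chemokine genes 2 rose and 6 fell, and the counts were also 2 and 6 when adjusted over the list alone. TNFSF10, the death ligand TRAIL, rose by 1.60 (SE 0.16), and IL10, an anti-inflammatory cytokine, fell by 1.80 (SE 0.31). CCL2, the ligand of CCR2, picked after its value was seen, rose by 1.46 (SE 0.31). Of 28 NF-kB pathway genes TLR4, the endotoxin receptor, rose by 1.06 (SE 0.13), and 3 fell, among them RELA, an NF-kB subunit, by 0.78 (SE 0.13) and the kinase gene MAP3K8 by 0.63 (SE 0.14). The third was BCL3 (log2 -0.61), picked after its value was seen, and over the NF-kB list alone 1 rose and 4 fell. SOD2, a mitochondrial superoxide dismutase, differed by 0.06 (SE 0.23). Neither list passed camera, with adjusted p of 0.380 for cytokines and 0.769 for the NF-kB list, although cytokines passed in the downward direction without donor 1, with a camera adjusted p of 0.0122. By edgeR the adjusted p was 0.00148 for TNFSF10, 0.0103 for IL10 and RELA, 0.00385 for TLR4 and 0.0236 for MAP3K8. The calls of CCL2 without donor 2 (0.0746) and BCL3 without donor 3 (0.179) were lost. Among the other cytokine genes that fell, picked after their values were seen, VEGFA lost its edgeR call without donor 1 or 2 (adjusted p up to 0.131). CXCL16 lost its call without donor 3 (0.0649).

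Of 37 interferon-response genes 5 rose and 0 fell, also when adjusted over the list alone. OAS1, a sensor of double-stranded RNA, rose by 1.12 (SE 0.15), IFIT3, an antiviral effector, by 0.90 (SE 0.15) and XAF1, a pro-apoptotic gene, by 1.12 (SE 0.22), and IFIT1 (0.64) and RSAD2 (0.70) were picked after their values were seen. In edgeR's quasi-likelihood test the adjusted p was 0.00519 for OAS1, 0.0103 for IFIT3 and 0.0166 for XAF1. The list median was 0.19, the camera adjusted p 0.0104, and the adjusted p = 0.537 with an estimated correlation. Of 8 NADPH oxidase genes, which make superoxide in phagocytes, 2 rose, the proton channel HVCN1 by 0.71 (SE 0.15) and the catalytic subunit CYBB by 0.63 (SE 0.16), and 4 rose when adjusted over the list alone. Lost calls by edgeR were those of IFIT1 without donor 1 or 2 (adjusted p up to 0.130), RSAD2 without donor 1 or 3 (0.143), HVCN1 without donor 3 (0.0955) and CYBB without donor 2 or 3 (0.186). The NADPH oxidase list had a camera adjusted p of 0.0111 and an adjusted p = 0.863 with an estimated correlation.

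Respiratory chain genes encoded in the nucleus did not pass as a list. Of 76 tested, 1 rose, 2 fell and 73 did not pass, and over the list alone 0 rose and 1 fell. NDUFV2, a complex I subunit, fell by 1.70 (SE 0.17), NDUFS7 fell by 0.80 (SE 0.20) and NDUFB3 rose by 0.75 (SE 0.17). NDUFV2 shares 28.4% of its exon bases with an overlapping gene and NDUFS7 shares 49.1% with genes on the opposite strand, so their counts are uncertain. NDUFS7 lost its edgeR call without donor 1 (adjusted p 0.103) and NDUFB3 without donor 1 or 3 (up to 0.0676). The list median was -0.02, with a camera adjusted p of 0.698, and without donor 1 the list passed in the downward direction with a camera adjusted p of 0.0122. The 13 messenger RNAs of the mitochondrial genome had a median of 0.31 and a camera adjusted p of 0.0117, with an adjusted p = 0.986 with an estimated correlation. None of these 13 passed by edgeR's quasi-likelihood test or over the list alone, and the values were 0.34 (SE 0.25) for MT-CO1, 0.28 (SE 0.22) for MT-ND1, 0.43 (SE 0.20) for MT-ATP8, 0.43 (SE 0.21) for MT-ND3 and 0.35 (SE 0.19) for MT-ND4L. The list median was 0.75 in donor 1, 0.11 in donor 2 and 0.11 in donor 3, and without donor 1 the camera adjusted p was 0.300.

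Of 26 genes for mitochondrial dynamics, biogenesis and mitophagy 1 rose and 2 fell, with the same counts over the list alone and a camera adjusted p of 0.698. The fission factor gene MIEF1 fell by 1.15 (SE 0.17), the mitophagy receptor gene BNIP3L by 0.51 (SE 0.13), and FUNDC1, another mitophagy receptor gene, rose by 1.35 (SE 0.27). Of 24 glycolysis genes 3 fell and 0 rose, also over the list alone. These were HIF1A, the hypoxia-inducible transcription factor, by 1.73 (SE 0.15), PFKFB3, an activator of glycolytic flux, by 1.07 (SE 0.14), and the glucose transporter gene SLC2A1 by 0.76 (SE 0.19). Adjusted p by edgeR was 0.000780 for HIF1A, 0.00444 for PFKFB3 and 0.0354 for SLC2A1. BNIP3L lost its call without each of the 3 donors (up to 0.223), and SLC2A1 without donor 1 or 3 (up to 0.0888). The glycolysis median was -0.14, the camera adjusted p 0.0289, and the adjusted p = 0.863 with an estimated correlation. Without donor 2 and without donor 3 the list lost its call, with camera adjusted p of 0.299 and 0.176.

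Of 8 genes for oxalate, glyoxylate and anion transport 0 passed by edgeR, and 0 over the list alone. The apical oxalate exchanger gene SLC26A6 differed by 0.32 (SE 0.19), the bicarbonate transporter gene SLC4A7 by -0.74 (SE 0.22), SLC26A11 by 0.51 (SE 0.17) and LDHA by -0.34 (SE 0.13). SLC4A7 passed at -0.99 without donor 2 and at -0.84 without donor 3, with edgeR adjusted p of 0.000930 and 0.0186. Of 13 crystal adhesion genes 0 passed, and MMP9 (-0.74, SE 0.24), FCER1G (0.37, SE 0.15) and NCL (-0.33, SE 0.14) had the smallest p. Of 33 antioxidant genes 1 fell, the autophagy adaptor gene SQSTM1 by 0.54 (SE 0.13), and 0 passed over the list alone. SQSTM1 lost its edgeR call without each of the 3 donors (adjusted p up to 0.0885), and HMOX1, the haem-degrading oxygenase, differed by 0.25 (SE 0.17). The camera adjusted p was 0.947 for transport, 0.947 for crystal adhesion and 0.698 for the antioxidant list.

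Of 31 genes for heat shock and the unfolded protein response 4 rose and 4 fell, and 6 rose and 9 fell over the list alone. HSPA1A and HSPA6, inducible chaperone genes, rose by 2.51 and 1.69 (SE 0.24 and 0.24), and DDIT4, a stress-induced inhibitor of mTOR signalling, fell by 2.23 (SE 0.16). HSPB1 and HSPA8 also rose, and SESN2, HERPUD1 and EIF2AK3 also fell, all picked after their values were seen. The edgeR adjusted p was 0.000902 for HSPA1A, 0.00577 for HSPA6 and 0.000253 for DDIT4, and the camera adjusted p was 0.698. Calls were lost for HSPB1 and EIF2AK3 without donor 1 (edgeR adjusted p 0.0609 and 0.0981), HERPUD1 without donor 2 (0.0770) and HSPA8 without donor 2 or 3 (up to 0.230). Of 30 immediate early genes 2 rose and 3 fell, and 2 rose and 4 fell over the list alone. DUSP6, a phosphatase of ERK, rose by 1.25 (SE 0.19), MYC by 0.86 (SE 0.16), and the transcription factor gene FOSL2 fell by 0.99 (SE 0.16), with a camera adjusted p of 0.371. ATF3 and NR4A2, the other members that fell, were picked after their values were seen and lost their edgeR calls without donor 2 (adjusted p 0.141 and 0.250). Without donor 3 the immediate early list passed in the downward direction, with a camera adjusted p of 0.0107.

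Among 15 replication-dependent histone genes 5 rose and 0 fell, and 6 rose over the list alone. The linker histone genes H1-4 and H1-2 rose by 1.54 (SE 0.25) and 0.80 (SE 0.18), and H4C5 by 1.45 (SE 0.36). The histone median was 0.68, the camera adjusted p 7.88e-05, and the adjusted p = 0.537 with an estimated correlation. Of 19 cell cycle genes MCM3 (0.67) and PCNA (0.69), both DNA replication factors, rose and 0 fell, also over the list alone. Of 36 autophagy and lysosome genes CTSL, a lysosomal protease, rose by 0.73 (SE 0.16), and the autophagy genes GABARAPL1 and ULK1 fell by 1.10 (SE 0.13) and 0.57 (SE 0.15), with the same counts over the list alone. Of 28 lipid genes 1 rose and 3 fell, and 4 fell over the list alone. IDI1, of sterol synthesis, fell by 0.79 (SE 0.13), the cholesterol exporter gene ABCA1 by 0.68 (SE 0.15) and the acyl-CoA synthetase gene ACSL1 by 1.28 (SE 0.28). Of 73 cytosolic ribosomal protein genes RPS10 fell by 1.05 (SE 0.27), with 39.4% of its exon bases shared with a readthrough gene, and 0 passed over the list alone. Calls lost with 1 donor left out, with the highest edgeR adjusted p, were PCNA without each of the 3 (0.129), MCM3 and RPS10 without donor 1 or 2 (0.0859 and 0.119), H1-2 and H4C5 without donor 1 or 3 (0.0549 and 0.220), ULK1 without donor 2 or 3 (0.230), ABCA1 without donor 2 (0.0874) and CTSL without donor 3 (0.0728). Members picked after their values were seen also lost their edgeR calls. These were the histone genes H2BC5 and H2BC8 without each of the 3 donors (adjusted p up to 0.137 and 0.184) and the lipid gene SLC25A20 without donor 2 (0.113). Of the 5 histone genes that rose, only H1-4 kept its call with each donor left out. The camera adjusted p was 0.698 for cell cycle, 0.947 for autophagy, 0.371 for lipid and 0.947 for ribosomal protein genes. The ribosomal medians were 0.41, -0.09 and -0.28 in donors 1, 2 and 3, and that list passed downward without donor 1 and upward without donor 3, with camera adjusted p of 0.000241 and 0.0279.

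Of 16 M1-type macrophage markers 0 passed by edgeR, and 0 over the list alone, and FPR2 (0.72, SE 0.22), CXCL10 (0.80, SE 0.25) and CD38 (0.56, SE 0.18) had the smallest p. FPR2 passed without donor 1 and CXCL10 without donor 2, with edgeR adjusted p of 0.0134 and 0.0372. Of 17 M2-type markers 2 rose and 2 fell, and 5 rose and 3 fell over the list alone. IL10 fell as given above, ARG1, the urea cycle arginase, fell by 1.35 (SE 0.30), and TGM2, a transglutaminase, rose by 1.15 (SE 0.25). ARG1 lost its edgeR call without donor 1 (adjusted p 0.0721) and TGM2 without donor 2 (0.0653). The camera adjusted p was 0.380 for the M1-type and 0.947 for the M2-type list. Median, mean and camera direction differed in sign for the lists of mitochondrial dynamics, cytokines, NF-kB, crystal adhesion, M2-type markers, ribosomal proteins and dendritic cells, none of which passed.

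**Figure D3:**
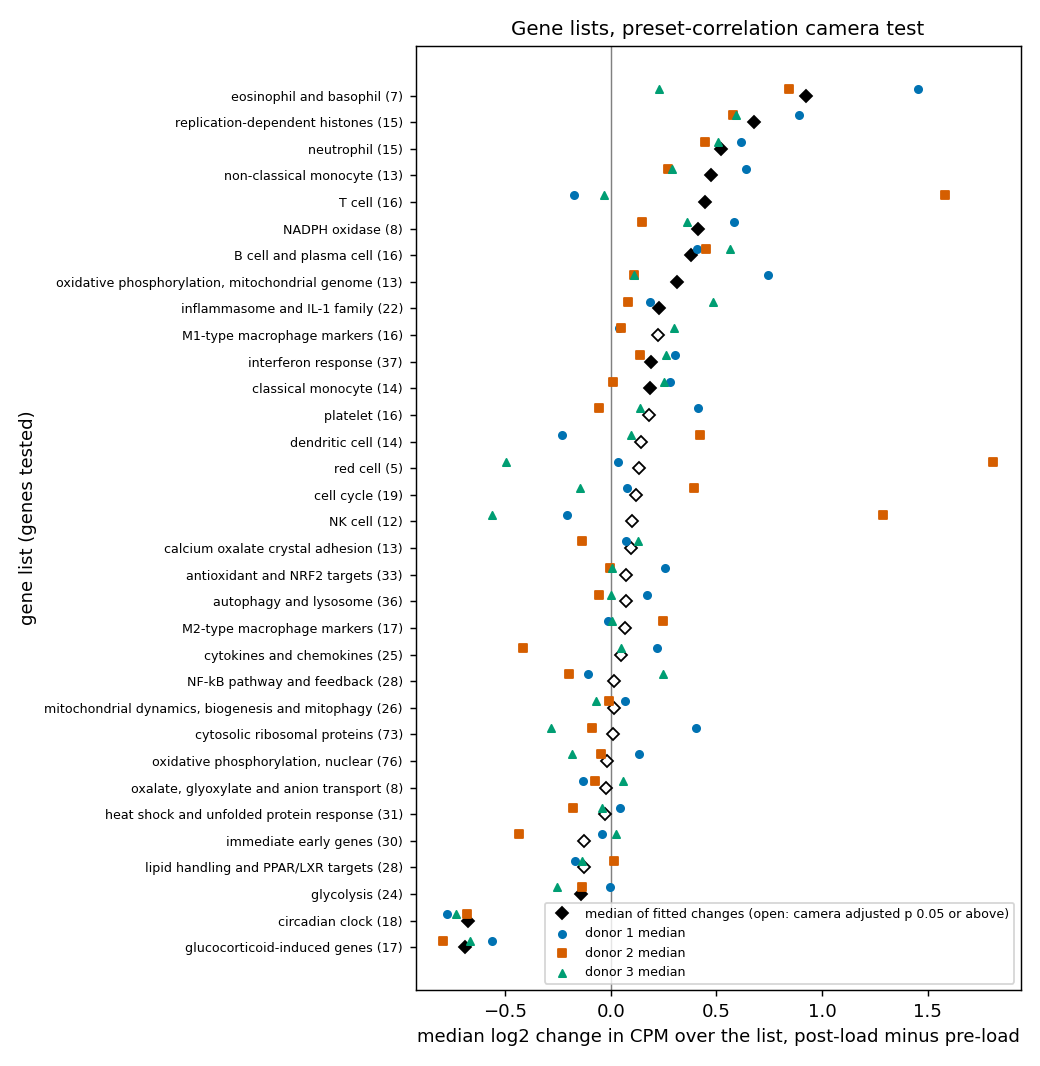
Median log2 change in CPM (x axis, post-load minus pre-load) of 33 gene lists (y axis, genes tested in parentheses), with diamonds for the fitted median, coloured symbols for the 3 donors and open diamonds where the camera adjusted p at the preset correlation was 0.05 or above. The clock (-0.68) and glucocorticoid-induced (-0.69) lists lie below 0 in the 3 donors, and the T cell list lies at 1.58 in donor 2 alone.

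CX3CR1 led the non-classical and CCR2 the classical monocyte markers. Of 13 non-classical markers 4 rose and 0 fell, and 5 rose over the list alone. CX3CR1 rose 6.42-fold, while FCGR3A, the CD16 receptor gene, rose by 0.59 on the log2 scale (SE 0.14) and LILRB1, an inhibitory receptor gene, rose by 0.69 (SE 0.17), and MS4A7 (0.52) was picked after its value was seen. Of 14 classical markers CCR2 alone rose, also over the list alone, and CD14 differed by 0.52 (SE 0.17). In edgeR's quasi-likelihood test the adjusted p was 0.0295 for FCGR3A, 0.0384 for LILRB1 and 0.0808 for CD14. The camera adjusted p was 5.02e-05 for non-classical and 0.0247 for classical markers, with an adjusted p = 0.537 with an estimated correlation for the former and 0.863 for the latter. Without donor 1 and without donor 3 the classical list lost its call, with camera adjusted p of 0.0534 and 0.0627. Calls were lost for FCGR3A and MS4A7 without donor 2 or 3 (edgeR adjusted p up to 0.0980 and 0.268) and LILRB1 without donor 1 (0.0754).

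Of 16 T cell markers TRAC, the receptor alpha constant gene, rose by 1.14 (SE 0.23) and CD2, an adhesion gene, by 0.83 (SE 0.20), also over the list alone. The T cell median was 1.58 in donor 2, -0.17 in donor 1 and -0.03 in donor 3. Its camera adjusted p was 0.0226, its adjusted p = 0.986 with an estimated correlation, and without donor 2 the median was -0.067. Of 12 NK cell markers 0 passed by edgeR or over the list alone, with medians of -0.21, 1.29 and -0.56 in donors 1, 2 and 3 and a camera adjusted p of 0.698, or 0.0398 upward without donor 3. Of 16 B cell markers IGHM rose by 0.96 (SE 0.17), also over the list alone, with a camera adjusted p of 0.0154 and an adjusted p = 0.537 with an estimated correlation. Of 15 neutrophil markers 4 rose and 0 fell, and 6 rose over the list alone. CXCR2, a receptor for CXCL8, rose by 1.79 (SE 0.29), CEACAM3 by 1.09 (SE 0.20) and KCNJ15 by 0.91 (SE 0.23), and TNFRSF10C (0.75) was picked after its value was seen. By edgeR, KCNJ15 and TNFRSF10C lost their calls without each of the 3 donors (adjusted p up to 0.107 and 0.162), TRAC without donor 1 (0.0877) and CD2 without donor 2 (0.0811). Of 7 eosinophil and basophil markers the transcription factor gene GATA2 rose by 1.40 (SE 0.25), also over the list alone. The camera adjusted p was 0.0111 for neutrophil and 0.0247 for eosinophil and basophil markers, with an adjusted p = 0.863 with an estimated correlation for each, and the latter list lost its call without donor 1 (0.0815) and without donor 2 (0.152).

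Of 14 dendritic cell markers the growth factor receptor gene FLT3 fell by 1.41 (SE 0.24), IRF8, a transcription factor gene, fell by 0.67 (SE 0.15) and the lectin gene CLEC10A rose by 0.55 (SE 0.15), with the same counts over the list alone. CLEC10A lost its edgeR call without each of the 3 donors (adjusted p up to 0.0790), and FLT3 and IRF8 without donor 1 (0.0608 and 0.0501). Of 16 platelet markers 0 passed, and GP1BA (-0.83, SE 0.27) and PPBP (0.45, SE 0.19) went opposite ways. Of 5 red cell markers 0 passed, and HBB differed by 0.27 (SE 0.77). GP1BA passed at -1.11 without donor 2 and HBB at 1.45 without donor 3, with edgeR adjusted p of 0.0119 and 0.000617. The HBB call rested on changes of 0.03 in donor 1 and 1.81 in donor 2, so its p does not measure the spread between donors. For platelet and red cell markers 0 passed over the list alone as well, and the camera adjusted p was 0.947 for dendritic cell, 0.698 for platelet and 0.769 for red cell markers. Across the 33 lists camera at the preset correlation called 14, of which 11 shifted up and 3 down. With an estimated correlation camera called 0, with 2 at an unadjusted p under 0.05. That test rests on the 2 residual degrees of freedom, so its 0 calls say little against a shift. By fry 0 were called, with 8 at an unadjusted p under 0.05 and 20 lists changed in either direction by its mixed test.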

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

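Of the 3 tests on mitochondrial transcripts, the comparison with nuclear respiratory genes was chosen after the result was seen, and the others before. Reads without a unique alignment, which the comparisons do not use, made up 24.7% of the post-load library of donor 1, above the 22.3% of the highest pre-load library. Reads that overlapped more than 1 gene, and were counted for none, made up 6.34% of the post-load library of donor 1. The post-load library of donor 2 had 6.35%, and both lay above the 6.03% of the highest pre-load library.

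The 13 messenger RNAs of the mitochondrial genome had higher medians after the load, by 0.75 in donor 1, 0.11 in donor 2 and 0.11 in donor 3. In donors 2 and 3 the 76 nuclear genes had medians of -0.044 (SE 0.029) and -0.185 (SE 0.040), below the bound of 0.1, so they did not rise with the mitochondrial messenger RNAs. The mitochondrial rise in these donors was itself close to 0.1, so they say little about its origin. In donor 1 the nuclear median was 0.134 (SE 0.057), above the bound, but it did not match the mitochondrial 0.75 in size. All protein-coding genes had a median of 0.066 in that donor, and ribosomal protein genes 0.41. A higher expression of the whole respiratory chain thus stays open in donor 1 only for a small part of the rise. The split by donor was made after the values were seen. These SE take genes as independent, although the estimated correlation of the nuclear list was 0.419. The pattern may rest on 1 donor's library pair, since without donor 1 the camera adjusted p was 0.300 (range over its alternatives 0.000108 to 0.986). Less unspliced nuclear RNA was tested on the 518 sense intronic and TEC gene models, a class of single-exon loci. Their medians were -0.597 (SE 0.062), -0.121 (SE 0.040) and -0.067 (SE 0.047) in donors 1, 2 and 3. The last lay above the bound of -0.1 set beforehand, so the prediction as written was not met in donor 3. It lay within its SE of the bound, a margin that the prediction did not include, and the explanation is left open on that margin alone. Reads in no annotated feature went from 21.4% to 10.1%, from 18.9% to 16.4% and from 16.9% to 16.3%. The load itself as an origin was not tested.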

How the results depend on the processing

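The GC and length offsets and the T cell marker score were chosen after the data were seen. The calls rested on the pairing: under no replicate block edgeR called 0 genes (0 higher, 0 lower), with 2523 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0762, while within the pairing DESeq2 called 1990 and limma-voom 1846. The change from 1686 genes followed the spread between donors, which then entered the error. Total counts alone gave 658 genes (250 higher, 408 lower), no filter 2957 (1322, 1635), the likelihood ratio test 2926 (1320, 1606) and a threshold of 0.10 gave 3098 (1441, 1657). The cause was not tested for total counts or the likelihood ratio test, and no filter tested more genes. Leaving out each donor gave 939 to 2231 genes, 436 to 909 higher and 503 to 1322 lower. The T cell marker score, in a fit with fewer residual degrees of freedom, gave 2439 genes, 1457 of them lower. No gene called with the donor block and TMM changed sign in any alternative. Lists shifted numbered 14 at first, 4 without the block, 9 with at least 50 counts in 3 libraries, 0 with an estimated correlation and 0 by fry, and 11 to 14 with each donor left out. Opposite directions (by camera for lists) with at least 1 of the values past the threshold were those of the T cell list without donor 2 (-0.067, range with each donor left out -0.067 to 0.72), ribosomal proteins without donor 3 (0.16, range -0.17 to 0.16) and HBB with the T cell score (-1.10), and the cause was not tested. Named genes short of the threshold also changed sign, among them IL1B (-0.28 to 0.37), NLRP3 (-0.49 to 0.18) and SOD2 (-0.30 to 0.34) over the alternatives. Of the named genes past the threshold 79 were lost without the block and 34 with total counts alone. In simulated data, 59% of changes by a factor of 2 were recovered, among genes above a minimum mean count.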

Other observations

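The gene families, the immediate early, glucocorticoid, non-classical and T cell marker tests and the counts of other splits were chosen after the results were seen. Members of the GIMAP family of immune GTPases rose together, 6 of 7 tested, with GIMAP4 at 4.26-fold (log2 2.09, SE 0.19) and GIMAP8 at 3.47-fold (log2 1.79, SE 0.21), while GIMAP2 (0.49) did not pass by edgeR. Of 8 toll-like receptor genes 5 rose, including TLR7 (log2 1.79, SE 0.17), an endosomal sensor of single-stranded RNA, and TLR4, while TLR2 differed by 0.07. Of 17 chemokine receptor genes 5 rose, including CCR1 (log2 1.48, SE 0.16), and CXCR4 fell, with chemokine receptor medians of 0.057, 1.12 and 0.357 in donors 1, 2 and 3. The family medians were 1.79, 0.86 and 0.37, and 1.73, 0.79 and 0.30 with total counts alone. Over these 3 families and ZNF genes, camera at the preset correlation gave adjusted p of 1.37e-22, 2.40e-08 and 3.29e-06, and the adjusted p = 0.0584, 0.108 and 0.0734 with an estimated correlation. The families were picked after members had been seen to rise in these same data. Their p-values are therefore descriptive and do not test the families.

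Of 434 zinc finger (ZNF) genes 60 rose and 17 fell, with a median of 0.23. The camera adjusted p of 5.02e-05, or adjusted p = 0.290 with an estimated correlation, is descriptive, as for the other families. Of 764 processed pseudogenes 4 rose and 55 fell, against 675 and 667 protein-coding genes (Fisher's exact test, two-sided, p = 2.43e-12, across genes, which are not independent). Antisense genes also fell more often than they rose, 79 against 26 (p = 4.29e-07, Fisher's exact test), but their medians were -0.306, -0.090 and 0.112 in donors 1, 2 and 3, against -0.308, -0.131 and -0.276 for processed pseudogenes. Sense intronic (22 lower, 6 higher) and TEC (23 lower, 6 higher) gene models went the same way, and a difference in unspliced RNA between libraries was not separated from these counts.

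The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 1686 genes and was the 1 split of 10 with as many, and the highest of the others was 0 by edgeR, with 80 to 2715 genes at an unadjusted p under 0.05. The donor block was kept in every split. A split that parts 1 pair thus tests that donor's own change. In the others that part all 3 pairs, a change shared by the donors enters the error, which lowers the count. The other splits therefore do not stand for unchanged data, and cannot tell the change from chance, for genes or lists. The real split gave 14 shifted lists, and 3 of the 10 splits gave as many, the highest of the others being 17. Among the 4 splits that part all 3 pairs, the others gave 0 genes and 11 to 17 lists, so the number of shifted lists did not set the load apart. Of the 14 lists, the clock, glucocorticoid, histone, non-classical and neutrophil lists had their smallest camera p in the real split, while each of the others had a p as small in 2 to 6 of the 10 splits, the real one included. The values were 1.74e-12 against 2.67e-07 at the lowest in other splits for the clock and 1.63e-13 against 4.51e-08 for the glucocorticoid list.

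The medians of the clock and glucocorticoid-induced lists lay below 0 in 3 of 3 donors, with 10 of 18 and 7 of 17 members lower past the threshold, and each list had an adjusted p = 0.398 with an estimated correlation. A later clock phase at the second sampling is a candidate explanation. The median of the PER and NR1D arm, with DBP, TEF and CIART, minus that of the BMAL1 arm was -0.857 (SE 0.504), -1.10 (SE 0.400) and -0.646 (SE 0.378) in donors 1, 2 and 3. However, the BMAL1 arm's own medians were -0.389, -0.043 and -0.282, and its member NFIL3 fell, a call lost without donor 2 (edgeR adjusted p 0.165). The arms were drawn from the clock list whose fall is in question, and PER1 is also a glucocorticoid-induced member. The difference therefore cannot tell clock phase from lower glucocorticoid exposure. Lower glucocorticoid exposure may also contribute: 12 genes left after removal of clock, immediate early and previously noticed members had medians of -0.500 (SE 0.309), -0.462 (SE 0.345) and -0.217 (SE 0.225), the last within its SE of 0, and 3 of the 12 passed. Handling or activation before lysis stays open, since 12 immediate early genes had medians of -0.296 (SE 0.228), -0.825 (SE 0.221) and 0.095 (SE 0.159), against -0.775, -0.679 and -0.732 for the clock list, and without donor 3 the 30 immediate early genes passed downward with a camera adjusted p of 0.0107. The load itself cannot be told apart from the later sampling time, since 0 of the 6 libraries came from donors sampled again without a load.

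CX3CR1, CCR2, GIMAP4 and GIMAP7 rose in 3 of 3 donors. A larger share of non-classical monocytes is argued against as the whole source of the CX3CR1 rise. The median of the other 12 markers lay 2.01 or more log2 units under CX3CR1 in each donor, and the classical marker CCR2 rose. A smaller gain in share stays open, since those medians were 0.614, 0.206 and 0.242 in donors 1, 2 and 3. CX3CR1 and CCR2 were picked as large rises in these same data, which partly set the gap and the CCR2 rise. More T or NK cells in the isolate are argued against in donors 1 and 3, where T cell markers had medians of -0.172 (SE 0.216) and -0.031 (SE 0.179) against 2.37 for the lower of GIMAP4 and GIMAP7 in each. They stay open in donor 2, with 1.58 (SE 0.125) for T cell and 1.29 for NK markers against 1.53 for the lower of the same genes. In that donor GIMAP7 rose by 3.75, CX3CR1 by 2.71 and CCR2 by 1.90, each above the T cell median. These 3 genes kept their edgeR calls with the T cell marker score as a covariate. That fit has fewer residual degrees of freedom, and its p-values measure the spread between donors poorly. Its smallest edgeR adjusted p was 4.65e-14, against 3.68e-05 without the score, so the kept calls are weak evidence. GC content or length bias is argued against by an adjusted p of at most 0.00323 for CX3CR1, CCR2, GIMAP4 and GIMAP7 with those offsets, although none of the 4 passed without the donor block. The load and the sampling time stay open as origins, and neither was tested.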
